A study of Mus musculus with 6 samples.

How the data were processed

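Each of 6 Affymetrix Mouse430_2 arrays was hybridised with labelled RNA from 1 pool of mouse calf muscle. Per the labels, RNA of 6 animals was combined in equal amounts for each pool, and 3 pools were made of each genotype, from 18 animals each. The pools are separate biological replicates per the labels, so the spread between arrays covers pools and arrays, and the spread between single animals is averaged within a pool. The p-values measure the spread between pools. Groups were taken from the genotype labels. The titles of the control arrays also carry the word intronic, whose meaning is not given in the sources used here, so that whether it sets these controls apart from other wild type mice is not known.

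The deposited values were a linear intensity per probe set, written by GCOS 1.1.1 per the submitters' processing notes. The algorithm and the scaling target are not given in the sources used here. From the values, the deposited intensity was scaled so that the mean after trimming 2% at each end was 150.0 on every array. Array medians were 34.0 to 38.4, and no detection calls were used. Scaling of this kind fixes the mean, so a shift shared by most transcripts cannot be seen. Signal near the top of the scanner's range can be compressed. The highest signal was 23547 to 23952 on the wild type arrays and 21386 to 22469 on the transgenic ones. The deposited files of run information, of other content than expression, were used only for array type, fluidics module and time of hybridisation. They showed 1 scan day, 2 rounds of hybridisation and 4 fluidics modules. Each round held arrays of both genotypes, and each module held arrays of a single genotype.

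Of 45101 rows, 64 control rows were left out. Signals were analysed as log2(signal + 16), a scale that understates the change of dim transcripts, and every fold given is on it. Probe sets were kept where the mean lay above the 40th percentile, a signal of about 21.7, which left 27022. The arrays were not normalized further. A linear model was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow an intensity trend, no covariates and two-sided tests. Benjamini-Hochberg adjustment ran over all kept probe sets, with a threshold of 0.05. The lists, tests, filters, alternatives and the rule for named genes were chosen before the data were examined, except where stated. Quality measures were tested by exact permutation.

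Gene names came from the platform's annotation, updated through gene identifiers to a RefSeq gene table of assembly GRCm38.p6, which was also used for which genes neighbour each other. Of the rows that were not controls, 34945 carried 1 symbol, 932 several and 9160 none, and 34741 of those with 1 symbol matched the table. No gene was named from a probe set with several symbols.

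The text covers the probe sets of Itga7 and Itgb1, with values per probe set for those kept, and every gene past the adjusted threshold. It also draws on the 12 higher and 12 lower genes with the smallest p among those whose arrays do not overlap, and on up to 4 members of each list with the smallest p. Of these, it gives the values of a part.

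Gene lists were tested with limma's camera at a preset correlation of 0.01 over the brightest kept probe set of each of 12942 genes. There were 23 gene lists and 12 marker sets of cell types, of which 34 had the 5 or more kept genes needed for the test, and adjustment ran over those. Camera with an estimated correlation and fry were alternatives. List members that were not matched to a probe set with 1 symbol were not analysed here. A list of endoplasmic reticulum genes and a list of amino acid response genes were written only after the called genes were seen.

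The fit was tested on a single run of simulated data for 27022 probe sets. Independent normal noise was set around the real means, with spreads drawn from probe sets of like mean. There, 12% of 50 probe sets changed by 0.5 on the log2 scale were recovered, 56% of 50 at 1, 86% of 50 at 1.5 and 88% of 50 at 2. Of 122 simulated calls 1 was false, and with no simulated change there were 0 calls and 0 of 34 lists. The simulated genes were independent of each other, which real genes of a list are not. The real data gave 33 calls, fewer than the simulated data. More calls loosen the Benjamini-Hochberg cut, so recovery in the real data may be lower. The number of arrays limits the precision. The alternatives were other offsets, normalizations, filters and variance models, array weights, blocks for replicate number, round and module, and leaving out each array. Figures were drawn with matplotlib.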

Results

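Transcript levels were measured in calf muscle (gastrocnemius and soleus) of female mice aged 5 weeks that overexpress integrin alpha7, and in wild type mice of the same background. Integrin alpha7 is a laminin receptor chain of the muscle fibre membrane. Each genotype was represented by 3 arrays, and each array carried RNA pooled from 6 animals, so that 18 animals stood behind each genotype. The arrays carried 45037 probe sets that were not controls. Their deposited signals had medians of 34.0 to 38.4 per array. Correlation over the 27022 probe sets kept was 0.971 to 0.981 between pairs of arrays, with a mean of 0.977 within the transgenic group, 0.978 within the wild type group and 0.976 between them. The question was which muscle transcripts differ when the integrin is overexpressed.

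The overexpressed gene itself was far higher in the transgenic arrays. The signal of Itga7 was 292 ± 32.7 (SD, n = 3) in wild type and 2238 ± 228 (SD, n = 3) in transgenic muscle, a 7.32-fold difference. On the log2(signal + 16) scale this was 2.87, with a 95% interval of 2.65 to 3.09 and an adjusted p of 1.67e-07 in limma's moderated test. Every transgenic array, at 2072 or more, lay above every wild type array, at 313 or less. Only 1 probe set measured Itga7, and the labels do not say which part of the gene the transgene carries. The partner chain Itgb1 was not called. Its brightest probe set gave 1001 in wild type and 813 in transgenic muscle, a log2 difference of -0.30 with an adjusted p of 0.274 over all genes and 0.0166 adjusted over the list alone. Its 2 other kept probe sets gave log2 differences of -0.24 and -0.21, and 3 more lay below the filter, with mean signals of at most 14.2. None of the remaining integrin chains passed over all genes, and of the 18 measured members of the integrin list 9 had positive and 9 negative differences.

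Besides Itga7, 19 named genes had a probe set that passed as higher in transgenic muscle and 5 had one that passed as lower. Among the higher ones were genes for proteins of the endoplasmic reticulum, the compartment in which membrane and secreted proteins fold. The chaperone Hspa5 rose 2.07-fold, from 2019 ± 107 to 4198 ± 401 (SD, n = 3), and a further probe set of Hspa5 gave 2.20-fold, while its dimmest one gave 1.05-fold with an adjusted p of 0.944. Manf, a secreted endoplasmic reticulum protein, rose 2.38-fold from 529 to 1286, the disulphide isomerase Pdia6 1.85-fold from 592 to 1104, and Herpud1, a protein of endoplasmic reticulum degradation, 1.61-fold from 1188 to 1914. Dnajb9, a co-chaperone, rose 1.59-fold, the calcium-binding chaperone Calr 1.59-fold and the chaperone Hsp90b1 1.47-fold. Adjusted p in limma was 0.000263 for Hspa5, 0.000562 for Manf and 0.0200 for Calr.

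Further higher transcripts were those of Pttg1, the securin of mitosis, at 2.94-fold and 2.61-fold on its 2 kept probe sets, and Mndal, an interferon-inducible nuclear protein, at 2.80-fold and 3.14-fold. Bcat2, the mitochondrial branched-chain aminotransferase, rose 2.11-fold, Shisa4 1.99-fold, Akr1e1 2.14-fold and Tpbgl 1.52-fold, and Ly6e rose from 923 to 1395. Rps4l gave 3.33-fold from a wild type signal of 16.9, below the filter's signal of about 21.7, so the size of its rise is uncertain. Its log2 difference ran from 0.94 to 2.68 over the alternatives that tested it, and it passed in 9 of 17. The lower probe sets were those of Csrp3, a muscle LIM protein of the Z-disc, at 0.608-fold from 2061 to 1243, Fbxo32, the atrophy-related ubiquitin ligase also called atrogin-1, at 0.633-fold, Pik3ca, a catalytic subunit of phosphoinositide 3-kinase, at 0.652-fold, the haem synthesis enzyme Alad at 0.530-fold and the chromatin protein Cbx1 at 0.543-fold. Adjusted p in limma was 0.0494 for Csrp3, 0.0281 for Fbxo32 and 0.0483 for Alad. The lower calls were less stable than most higher ones. Over 18 alternatives of scaling, filter, variance model, block and left-out array, Csrp3 passed in 7, Pik3ca and Cbx1 in 9, Alad in 10 and Fbxo32 in 11. Without wild type replicate 1, 0 probe sets passed as lower, and without wild type replicate 2 only 1 did.

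Probe sets of the same gene disagreed for several called genes. For Rgs5 the called probe set gave 2.22-fold, while the brightest one gave 1.09-fold with an adjusted p of 0.636. For Marcksl1 the called probe set gave 2.51-fold and a brighter one a log2 difference of -0.12. For Cbx1 the called probe set gave a log2 difference of -0.88 and brighter ones 0.02 and 0.02. For Pink1 the called probe set gave 1.57-fold, and a brighter one a log2 difference of -0.08. For C1qtnf12 the called probe set gave 1.79-fold, and brighter ones log2 differences of 0.28 and 0.06. For Fbxo32 a brighter probe set gave a log2 difference of -0.18, and the brightest one 0.657-fold with an adjusted p of 0.185.

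**Figure D1:**
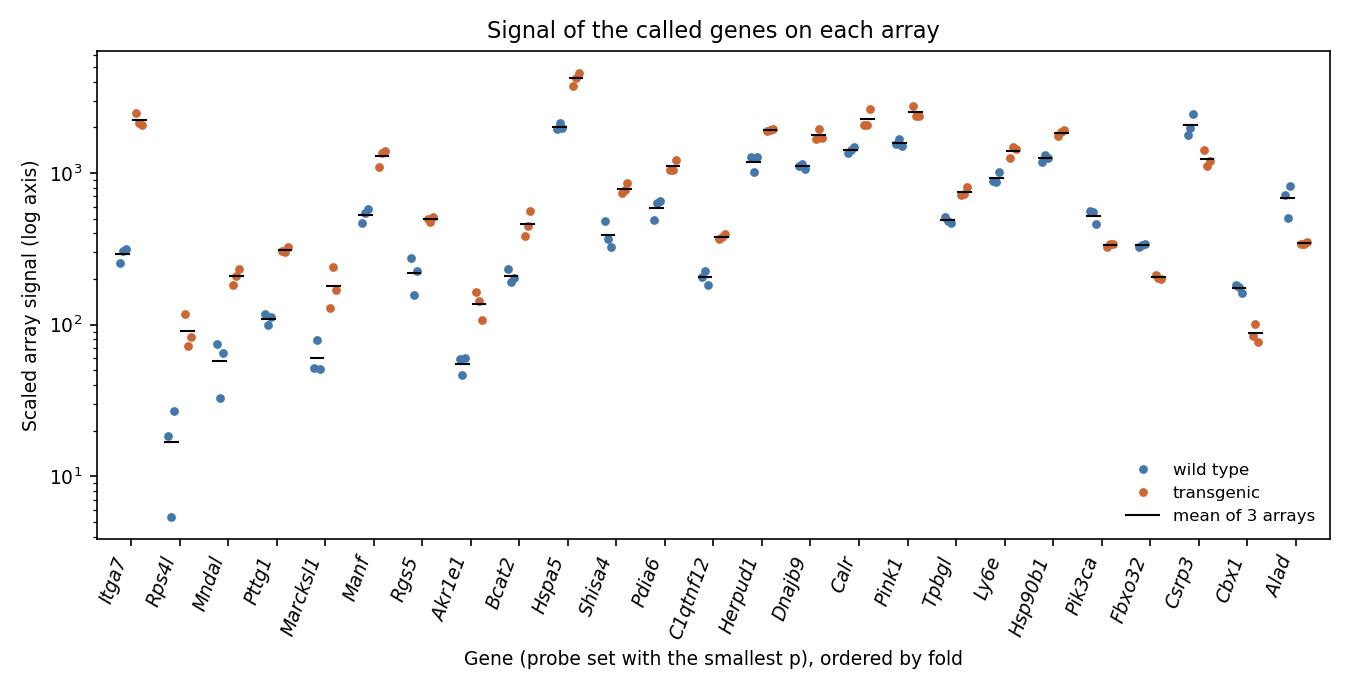
Scaled array signal (log axis) of the 25 named genes past an adjusted p of 0.05, for the probe set with the smallest p, ordered by fold. Points are single arrays, 3 per genotype, and bars are means; for Itga7 the transgenic mean is 2238 and the wild type mean 292.

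In all, 33 probe sets of 27022 passed an adjusted p of 0.05 in limma, 27 higher and 6 lower in transgenic muscle. Of these, 28 carried a single gene symbol and named 25 genes, 2 carried several symbols and 3 carried none. At least 2-fold higher were 13 probe sets, and 0 were at least 2-fold lower. At an unadjusted p under 0.05 there were 2121 probe sets, where 1351.1 would be expected with no difference. Other splits of the 6 arrays into 3 and 3, which mix the genotypes, gave 924 to 1560 at this threshold. The arrays of the genotypes did not overlap for 3609 probe sets, 13.4% of those tested, where chance gives 10%. Genes that came next among the lower ones but did not pass included Sympk, Slc1a5 and Dcn, the matrix proteoglycan decorin, which gave 0.805-fold with an adjusted p of 0.0879 (a dim probe set of Dcn gave a log2 difference of 0.45). The median half-width of the 95% interval was 0.37 on the log2 scale, and for 92.2% of probe sets the whole interval lay within 1 log2 unit of no difference. The count depended on the variance model, since 1 probe set, that of Itga7, passed without the intensity trend, and it was 17 with no filter on dim probe sets and 50 with equal array medians. It was 19 without wild type replicate 1 and 18 without wild type replicate 2. With the fluidics module as a random block it was 297, but each module held a single genotype and the correlation within modules was -0.44.

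**Figure D2:**
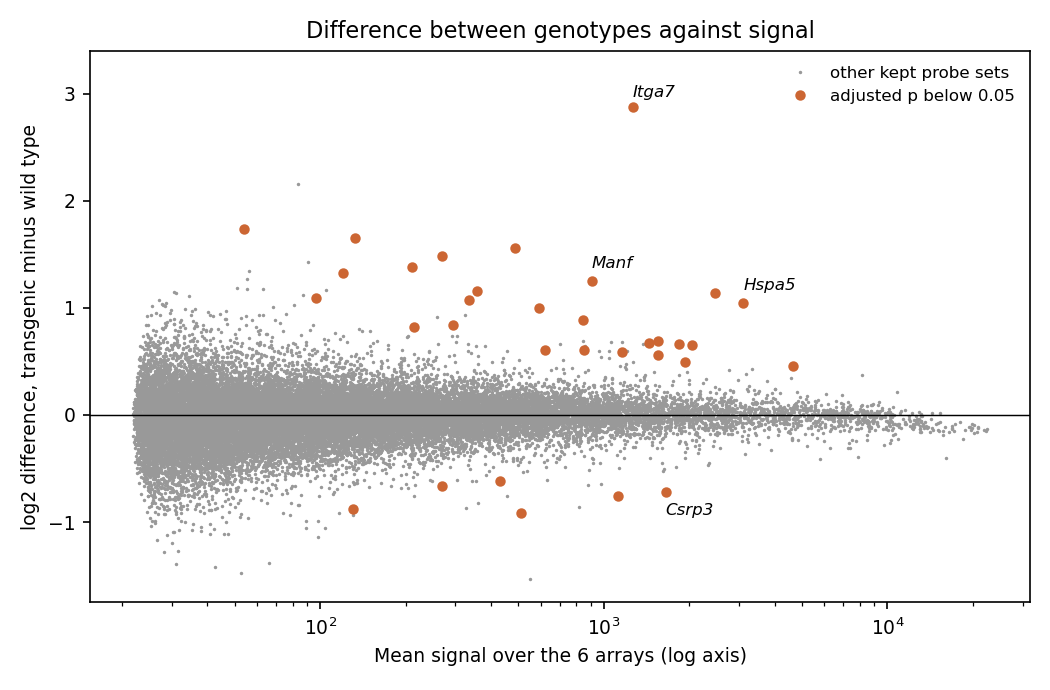
Log2 difference between transgenic and wild type muscle against the mean signal over the 6 arrays (log axis) for 27022 probe sets. Orange points are the 33 probe sets past an adjusted p of 0.05, of which 27 lie above 0 and 6 below.

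Contractile and metabolic gene groups showed small shifts in the camera test of limma, which compares a list with all other genes. Of 34 lists and marker sets, 7 passed an adjusted p of 0.05 with the preset correlation between genes, and 0 passed with an estimated one. With the preset correlation, each of the other 9 splits of the arrays, which mix the genotypes, also called 2 to 11 lists. A small p from this test therefore does not by itself set the genotypes apart. The fast fibre list was lower, with a median log2 difference of -0.11 over 22 genes and an adjusted p of 6.37e-08, and adjusted p = 0.665 with an estimated correlation. None of its members passed over all genes, and 9 were lower adjusted over the list alone, among them Tpm1, a thin filament tropomyosin, at 0.855-fold and the myosin light chains Myl1 at 0.894-fold and Mylpf at 0.903-fold. The wild type mean signals of these genes were 19987.2, 21869.7 and 23430.5, toward the top of the range, where signal can be compressed. With quantile normalization the fast fibre median was -0.00 and the adjusted p 0.916, the highest value over the alternatives, whose lowest was 9.20e-10. The oxidative phosphorylation list was lower, with a median of -0.06 over 38 genes and an adjusted p of 0.000181, and adjusted p = 0.727 with an estimated correlation. None of its members passed over all genes and 1 was lower adjusted over the list alone, the complex III subunit Uqcrc2 at 0.808-fold. The list lost its call with quantile normalization, at an adjusted p of 0.189, and with equal array medians, at 0.149. It was also lost in hybridisation round 1 alone, a restriction chosen after the results were seen, at 0.351, and the range over the alternatives was 9.08e-08 to 0.727.

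The calcium handling list was lower, with a median of -0.07 over 29 genes and an adjusted p of 0.00792, and adjusted p = 0.665 with an estimated correlation. None of its members passed over all genes or adjusted over the list alone. Trdn, the triadin of the calcium release complex, gave 0.879-fold, while a dimmer probe set of Trdn gave 1.11-fold, and the calcium pump Atp2a1 0.928-fold. Its call was lost without wild type replicate 2, at an adjusted p of 0.0534, and without transgenic replicate 2, at 0.0546, and also with equal array medians, at 0.149, without the intensity trend, at 0.0660, and with the mean of a gene's probe sets, at 0.102. Over the alternatives the adjusted p was 0.000609 to 0.665.

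Genes of regenerating and embryonic muscle were higher as a list, with a median log2 difference of 0.22 over 18 genes and an adjusted p of 0.0127, and adjusted p = 0.727 with an estimated correlation. None passed over all genes, and adjusted over the list alone 2 were higher and 1 lower. The perinatal myosin heavy chain Myh8 gave 2.17-fold, from a wild type signal of 51.6, the embryonic light chain Myl4 gave 1.29-fold, and the cardiac actin Actc1 gave 0.876-fold. The list's call was lost without wild type replicate 2, at an adjusted p of 0.0534, and without transgenic replicate 1, at 0.387, over a range of 0.000352 to 0.727.

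The immediate early list was higher, with a median of 0.10 over 24 genes and an adjusted p of 0.0166, and adjusted p = 0.665 with an estimated correlation. Its members Zfp36, which promotes mRNA decay, and Socs3, an inhibitor of cytokine signalling, gave 1.36-fold and 1.33-fold, and none passed over all genes or adjusted over the list alone. Its call was lost without wild type replicate 1, at an adjusted p of 0.0645, wild type replicate 3, at 0.0689, transgenic replicate 1, at 0.213, and transgenic replicate 2, at 0.0684, over a range of 0.000835 to 0.665. The interferon response list was higher, with a median of 0.14 over 24 genes and an adjusted p of 0.0280, and adjusted p = 0.855 with an estimated correlation. Again none of its members passed over all genes or adjusted over the list alone, Rsad2 giving 1.28-fold on its brightest probe set and 0.876-fold and 0.895-fold on dimmer ones. Its call was lost without wild type replicate 3, at an adjusted p of 0.200, transgenic replicate 2, at 0.735, and transgenic replicate 3, at 0.0661, and also with the filter at the 60th percentile, at 0.0593, without the intensity trend, at 0.0627, and with array weights, at 0.0815. In hybridisation round 1 alone it was 0.242, and the range over the alternatives was 4.09e-05 to 0.855.

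**Figure D3:**
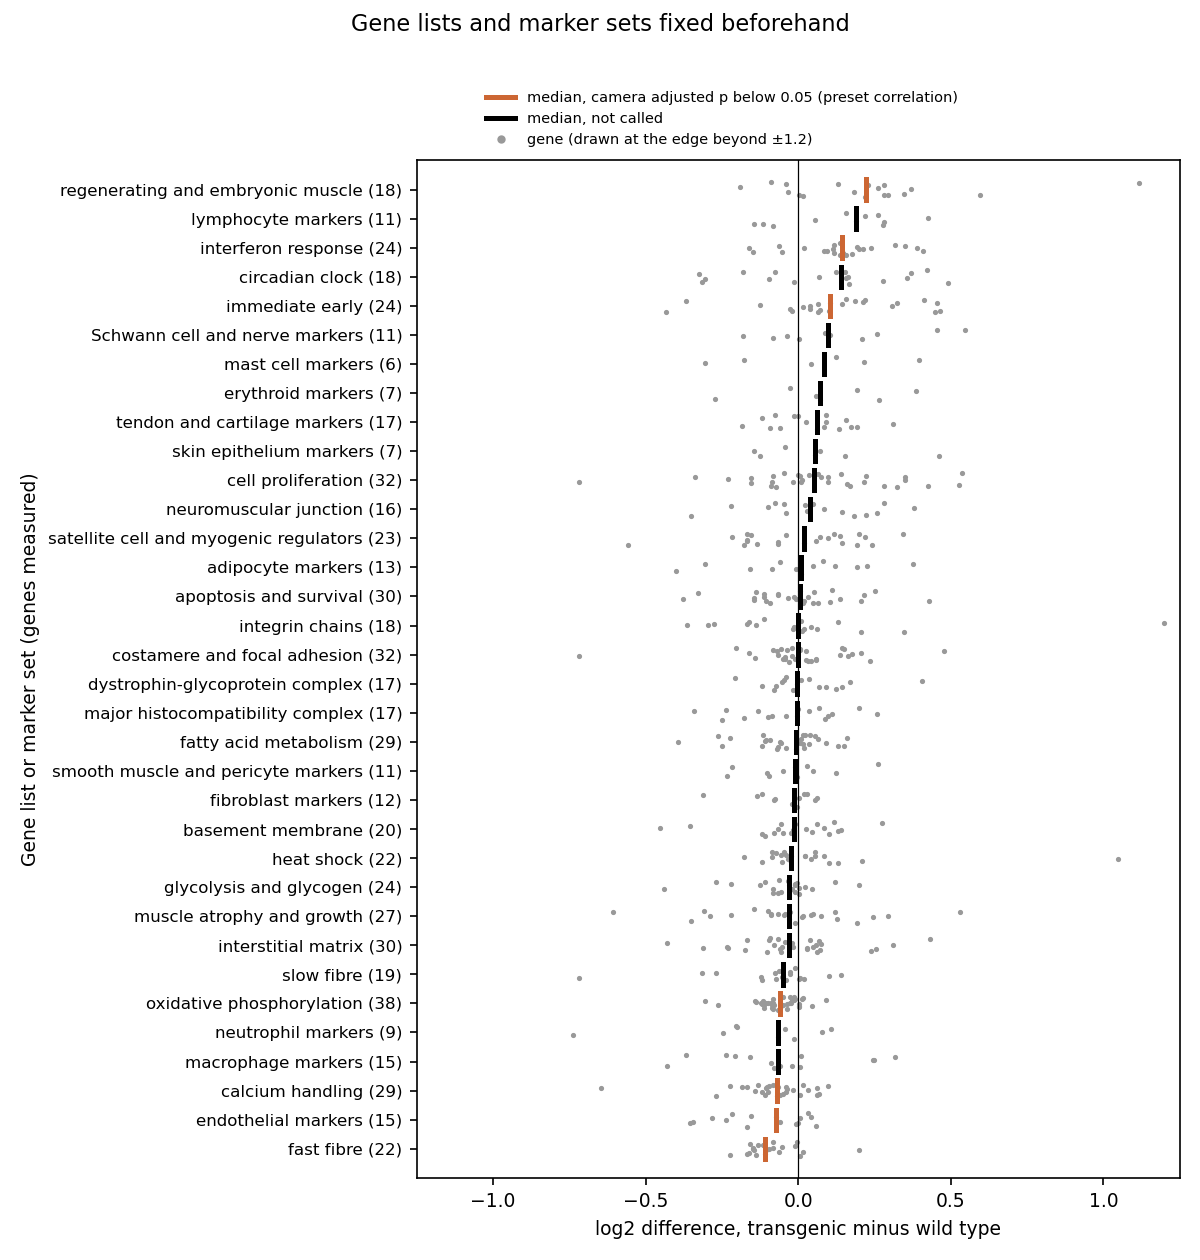
Log2 difference between transgenic and wild type muscle for the members of each gene list and marker set, with the number of genes measured in brackets. Points are genes and bars are medians, orange where the camera adjusted p was below 0.05; the medians run from -0.11 for the fast fibre list to 0.22 for the regenerating and embryonic muscle list.

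Several groups that the biology of the integrin would bring to mind were not called by camera. The adjusted p was 0.955 for integrin chains, 0.756 for the dystrophin-glycoprotein complex, 0.798 for costamere and focal adhesion genes, 0.798 for the basement membrane and 0.756 for the interstitial matrix. Within these lists, Itga7 passed over all genes among the integrins and Csrp3 among the costamere genes, and adjusted over the list alone Dcn was lower in the interstitial matrix. No member of the dystrophin complex or the basement membrane passed, over all genes or adjusted over the list alone. Dystrophin itself, Dmd, gave 0.866-fold with an adjusted p of 0.655. Satellite cell and myogenic regulators gave an adjusted p of 0.955, apoptosis and survival genes 0.874, cell proliferation genes 0.161 and neuromuscular junction genes 0.715, and none of their members passed over all genes or adjusted over the list alone. The slow fibre list, to which Csrp3 also belongs, gave 0.115 and muscle atrophy and growth genes 0.755, where Fbxo32 was lower adjusted over the list alone. The heat shock list, which holds Hspa5, gave 0.756. Glycolysis and glycogen genes gave 0.115, fatty acid metabolism genes 0.665, and the major histocompatibility complex 0.756, with no member past either threshold. Circadian clock genes gave 0.138, and there the clock output gene Dbp, at 1.40-fold, was higher adjusted over the list alone.

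Some of these lists were called when 1 array was left out. The slow fibre list, with Csrp3, was lower without wild type replicate 1, at an adjusted p of 0.0135, transgenic replicate 1, at 0.000889, and transgenic replicate 3, at 0.0107. The interstitial matrix, with Dcn, was lower without transgenic replicate 3, at 0.00265, and in hybridisation round 1 alone, at 0.00251. Without transgenic replicate 1, proliferation genes were higher, at 0.0323, and glycolysis genes lower, at 0.0370. Circadian clock genes were higher without transgenic replicate 3, at 0.0362. The median and the camera direction differed in sign for several uncalled lists. For integrin chains, the dystrophin complex, costamere genes and heat shock genes the median was negative and the test upward, and for satellite cell genes, apoptosis genes and adipocyte markers the median was positive and the test downward. The mixed fry test, which asks for change in either direction, called 7 lists. They were fast fibre, immediate early and endothelial genes and 4 that camera did not call, namely integrin chains, with Itga7, at an adjusted p of 4.60e-05, heat shock genes, with Hspa5, at 0.00154, proliferation genes, at 0.00993, and satellite cell genes, at 0.0459.

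Endothelial markers were lower, with a median log2 difference of -0.07 over 15 genes and an adjusted p of 0.0284, and adjusted p = 0.727 with an estimated correlation. None passed over all genes and 1, the angiopoietin receptor Tek, at 0.782-fold, was lower adjusted over the list alone. Their call was lost without wild type replicate 2, at an adjusted p of 0.239, wild type replicate 3, at 0.0893, transgenic replicate 1, at 0.157, and transgenic replicate 2, at 0.130, and also with equal array medians, at 0.0647, over a range of 0.00315 to 0.727. Lymphocyte markers were not called, at an adjusted p of 0.161, although their median log2 difference of 0.19 over 11 genes was larger in size than that of 6 of the 7 called lists. Of these 11 genes 8 had positive differences, none passed over all genes or adjusted over the list alone, and the directional fry test gave an unadjusted p of 0.0345 and an adjusted p of 0.391. The other marker sets were not called, with adjusted p of 0.872 for adipocytes, 0.400 for macrophages, 0.417 for neutrophils, 0.798 for smooth muscle and pericytes and 0.162 for fibroblasts. It was 0.417 for tendon and cartilage, 0.138 for Schwann cells and nerve, 0.303 for erythroid cells, 0.756 for mast cells and 0.756 for skin epithelium. Leaving out transgenic replicate 3 gave lower fibroblast markers, at an adjusted p of 0.00503, and leaving out transgenic replicate 2 gave higher tendon and cartilage markers, at 0.0275. In hybridisation round 1 alone, fibroblast markers were lower, at 0.0127, as were macrophage markers, at 0.0227. In the adipocyte set, Car3, which muscle also expresses, was lower at 0.758-fold and Ucp1 higher, at 1580 against 1219, both adjusted over the list alone. Of the sex-linked list only Xist was kept, at 0.755-fold with an adjusted p of 0.573, and its brightest probe set gave at least 716 on every array, while 9 Y-linked probe sets gave at most 21.6.

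None of 10 measures of array and RNA quality differed between genotypes in an exact two-sided permutation test, whose smallest possible p with 3 arrays against 3 is 0.10. The smallest p was 0.2, for the actin 3'/5' ratio and for the bioC and dap control transcripts. The highest signal of an array was not among these measures. It was lower on every transgenic array, at 21386 to 22469, than on the wild type arrays, at 23547 to 23952. Transgenic replicate 3 stood apart on the first principal component, at 42.9 against -20.1 to 3.7 for the other arrays, and carried the lowest bioC signal, 399 against at least 514 on the other arrays.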

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

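The restriction to hybridisation round 1 was chosen only after the results were seen, while all other alternatives here were fixed before. Itga7 kept its direction and passed under all 18 alternatives fixed before, at log2 differences of 2.69 to 2.94, and leaving out single arrays gave 2.78 to 2.93. The 33 called probe sets kept their sign under every alternative that tested them. For all 33 the arrays of the genotypes did not overlap, so leaving out an array could not turn the sign. Other filters and variance models leave the difference as it is, so the kept signs say little about stability. The count was 33 in the main setting, 50 with equal array medians (32 shared), 17 with no filter on dim probe sets, 1 with no intensity trend and 297 with the fluidics module as a random block. That last fit had a correlation of -0.44 within modules, and each module holds 1 genotype and at most 2 arrays. A negative correlation of this kind narrows the standard error of the genotype difference, so that count is no sign of more differences. Leaving out single arrays gave counts from 18 to 39. With other thresholds it was 63 at an adjusted p under 0.1 and 2121 at an unadjusted p under 0.05. The filter alternative tests more and dimmer probe sets, and the cause of the remaining changes was not tested. Round 1 alone gave 28, of which 15 were shared. Of the 28 called probe sets with a single symbol, 1 passed under every one of these 18 and 16 under at least 14 of them. The replicate block gave 36 calls, of which 28 were shared. After the group means were removed, arrays with the same replicate number correlated at 0.00, 0.06 and 0.05, all under 0.1, and the transgenic arrays 2 and 3, but not 1, correlated best with the wild type array of their own number, so the numbers were not taken to pair arrays.

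The lists called numbered 7 in the main setting, 4 with equal array medians, 0 with an estimated correlation 0 with the directional fry test and 7 with the mixed one, and 4 to 10 when single arrays were left out. With quantile normalization the fast fibre median went from -0.11 to -0.0013 (adjusted p 0.916, camera direction up); quantile normalization sets the brightest values of all arrays equal, and these transcripts are among the brightest. Dim signal limits what can be seen, since probe sets below the 40th percentile were tested only in the alternative with no filter.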

Other observations

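The tests of the endoplasmic reticulum and amino acid response lists, the test of members outside the 70 smallest p, the tests of single muscle lists after quantile normalization, matching to the 50 nearest genes, the fibroblast and lymphocyte markers each alone, the count of probe sets in other splits and the comparison of probe sets within a gene were chosen only after results were seen. The called genes prompted a list of 47 endoplasmic reticulum folding and export genes, all of them measured. Of these, 7 were higher over all genes, 22 were higher adjusted over the list alone, and 44 had positive differences, with a median log2 difference of 0.27. Among members not called over all genes, Xbp1, a transcription factor of the unfolded protein response, gave 1.32-fold on its brightest probe set and 0.802-fold on its dimmest, Creld2 1.59-fold, Sdf2l1 1.58-fold and the oligosaccharyltransferase subunit Ddost 1.43-fold, while Edem1 gave 0.847-fold on its brightest probe set and 1.09-fold on another, and Ero1a 0.851-fold. The list's median was 0.25 in hybridisation round 1 and 0.37 in round 2, which held only replicate 3 of each genotype. It was at most 0.14 in size in the other 9 splits of the arrays. Those splits mix the genotypes and the list was written from the called genes, so smaller medians there add no support. Of 23 measured genes of the amino acid response, 0 passed over all genes, and the median was 0.12, with a camera p of 0.0128 and p = 0.0542 with an estimated correlation. These genes were named after their values were seen.

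Higher endoplasmic reticulum transcripts were weighed against scaling and against other cells. The list's median lay at the 100th percentile of 10000 random lists matched on signal. The list was written from the called genes and holds them, so this percentile cannot decide on distortion with intensity. The median log2 difference was 0.23 for the members that were not called, which were not matched on signal by themselves. Over all kept probe sets, however, the median log2 difference per decile of signal was only -0.05 to 0.01. After quantile normalization all 33 called probe sets were still called. Distortion with intensity would move genes of like signal alike, so these values argue against it as the cause of the rise. The mean of 23 fibroblast and lymphocyte markers was 0.0412 ± 0.0364 (SE) against a median of 0.69 for the called members. Fibroblast markers alone gave -0.05 ± 0.03 (SE over genes) and lymphocyte markers 0.14 ± 0.06 (SE over genes). These errors hold no spread between pools. Of 11 lymphocyte markers 8 had positive differences, while the brightest, Ighm, gave -0.12. The markers gave no sign of more fibroblasts, and a rise in lymphocytes stays open. The 40 members that were not called were also shifted upwards (camera p = 4.03e-19, p = 0.00853 with an estimated correlation), as were the 37 outside the 70 probe sets with the smallest p (camera p = 1.78e-15, p = 0.0151 with an estimated correlation). A genotype effect on the wider list may be the reason, as a hypothesis, since the list was found and tested on the same arrays, and each fluidics module held a single genotype, so an effect of the module stays open too.

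Lower fast fibre, oxidative phosphorylation and calcium handling transcripts may partly reflect compression or scaling at the bright end. The 119 probe sets above a signal of 10000 had a median of -0.08. Members of these lists, such as Tpm1, Myl1 and Atp2a1, are among them, so that median is not separate evidence. The medians of 2 of the 3 lists lay below the 2.5th percentile of random lists matched in signal bins. Fast fibre lay at the percentile 0.42 and calcium handling at 0.72, with oxidative phosphorylation at 17.2. With genes of the fibre, calcium and energy metabolism lists left out of the random lists, the percentiles were 0.29, 0.52 and 9.12. With matching to the 50 nearest genes, chosen later, the percentiles were 2.32, 0.42 and 9.27. After quantile normalization the adjusted p was 0.916 for fast fibre, 0.189 for oxidative phosphorylation and 0.0389 for calcium handling, whose median was then -0.06 against -0.07 before. For calcium handling, these values argue against distortion with intensity as the whole cause. Both tests treat genes as nearly independent, however, and with an estimated correlation that list was not called (camera adjusted p 0.665). Scaling may account for the oxidative phosphorylation shift, and for fast fibre the tests differ, so that scaling and genotype cannot be told apart.

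Some calls may come from the chromosome around a gene or from single probe sets. Genes with a p below 0.001, 105 in number, formed 17 pairs within 1 Mb of each other, against a mean of 8.59 in random draws, and a share of 0.0044 of 10000 draws had as many. A chromosome segment that differs between the genotypes would give such pairs. The paired genes fell into many groups more than 1 Mb apart, and Itga7 was not among them, so a single short segment would not give them all. Neighbours that are regulated or measured together, such as Pink1 and Ddost, which lie within 1 kb, would also give pairs. Genes were taken by the smallest p of any of their probe sets, while the draws took all genes alike. In 6 of the 9 called genes with a brighter probe set, the interval of a brighter one excluded the called difference, as hybridisation particular to one probe set would give. A strain variant under a probe was not tested, since probe sequences were not used here.

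With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 33 probe sets and the highest other split 1, so that 1 of the 10 splits gave as many. The other splits mix the genotypes, so that differences such as that of Itga7 widen the spread within their groups. Their lower counts of probe sets therefore add no support. For the gene lists the real split gave 7 and the highest other split 11, so that 2 of the 10 splits gave as many. Every other split called at least 2 lists.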
